A study of Homo sapiens with 6 samples.

How the data were processed

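RNA was measured in 6 libraries of the CUTLL1 line, 3 exposed to agarose carrying T3 and T4 and 3 to agarose alone, each for 24 hours. Per the labels' protocols, total RNA was treated with DNase, poly(A) RNA was selected with oligo-dT beads, and libraries were made with an Illumina TruSeq RNA kit. The authors deposited whole-number read counts per gene symbol, without normalisation, for 23368 genes, of which 4637 had no read in any library. Per the submitters' processing notes, TopHat, HTSeq and edgeR were used with the genome build hg19. Their versions, the annotation, the handling of strand and of reads that match several genes are not given in the sources used here. Reads shared between overlapping genes, antisense genes or near-identical copies therefore cannot be separated, which concerns ribosomal protein genes with their many processed pseudogenes, histone genes, and HSPA1A with HSPA1B. No row lacked a gene name. Poly(A) selection favours intact, polyadenylated RNA, so replication-dependent histone genes are measured poorly and degraded RNA can be lost in proportion to transcript length.

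The authors also deposited a table of the same comparison with a log2 fold change, a p-value and an adjusted p-value per gene. Per the file headers the fold change is that of hormone-bound agarose over the control, and edgeR is the tool named in the submitters' processing notes. Its normalisation, dispersion and test are not given in the sources used here. It lists all 23368 genes, so no gene had been filtered out. Gene names stored as dates, 13 in number, were left out of the correlation with the values computed here. Its column of mean expression was not used because many cells held a spreadsheet error.

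Depth ranged from 7065362 to 24383589 counted reads. A gene with 0 reads may be present at up to 3 reads, which is between 0.123 CPM of the library total in the deepest and 0.425 in the shallowest library, or 0.117 and 0.580 normalised CPM. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. The chi-square statistic per degree of freedom between libraries of a group was at least 9.37, so no pair of libraries within a group was a duplicate within sampling noise.

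Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings, library sizes were scaled with TMM, and glmQLFit and glmQLFTest with the version's defaults compared the groups, two-sided, with Benjamini-Hochberg adjustment over 13991 genes and a threshold of 0.05. Correlations between libraries used log2 CPM with a prior count of 2, and deviations of a list in a library are medians of log2(CPM + 0.5) minus the mean of the agarose libraries. A fold change that fails this threshold is given as a value. The TMM factors were 1.05, 1.07 and 1.06 for the agarose libraries and 1.07, 1.08 and 0.733 for the hormone-bound agarose libraries. The median log2 fold change of all genes was 0.027 with TMM and -0.10 with library totals alone, so directions are relative to that shift. Standard errors are the size of the log2 fold change divided by the square root of the F statistic, and 95% intervals use the test's degrees of freedom. The median SE was 0.30 over 6 libraries and 0.16 without hormone-bound agarose replicate 3. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so none was run.

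A set of 28 gene lists was written before the data were examined, from the study's title, the cell type, general cell states and other cell types. Camera from limma 3.58.1 with a preset correlation of 0.01 compared each list that had at least 5 genes tested with all other genes, with adjustment over 23 lists. Camera with a correlation estimated per list, and fry, which tests a list on its own, were run beside it. B-cell, myeloid, erythroid, and stromal and endothelial markers had fewer than 5 genes tested and are given as summed CPM of the library total. Of 13 mitochondrially encoded genes 0 were in the table. ITGAM is in both the integrin and the myeloid list.

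Also fixed before the data were examined were the design, the alternatives and the genes to be named. The rule named the 10 genes with the largest rise and fall past the threshold, or, as none passed, the 10 with the smallest p-values, then ITGAV, ITGB3, VEGFA, VEGFB, VEGFC, THRA, THRB, KLF9, CCND1, PCNA, MKI67, MYC and NOTCH1 whatever their values, and up to 4 genes per list with the smallest p-values. EDEM3, NEAT1, MIAT, PTK2B, EPHX2, ITGA4, ITGB1, ITGB5 and GZMA were named after their values were seen. Alternatives set in advance were DESeq2 size factors or library totals in place of TMM, no low-count filter or a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, edgeR's exact test, limma-voom, a replicate block, each library left out in turn, a fold of at least 1.5, and an adjusted p under 0.01. After hormone-bound agarose replicate 3 was seen to stand apart, limma-voom with library quality weights, offsets for transcript length and GC content, the quasi-likelihood test without its legacy option, the other tests without that library, and an estimated correlation in further settings in which a list had passed were added. The quality weights were 1.10, 1.41 and 6.13 for agarose replicates 1, 2 and 3. For hormone-bound agarose replicates 1, 2 and 3 they were 0.744, 2.02 and 0.0704. That fit therefore rests mainly on agarose replicate 3 and hormone-bound agarose replicate 2. Transcript length and GC content came from a GENCODE annotation of a later genome build, matched by gene symbol for 20203 of the 23368 genes, and no coordinates are given because that build differs from hg19. For the correction, each library's trend with length and GC content was fitted against the mean of the other libraries in the fit. Such a trend is larger than that against the mean of all libraries, so the correction overshoots. The tested genes nearest to CHRNA2 on either side were taken from a RefSeq gene table of the assembly GRCh38.p14.

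The steps were tested on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed. The changed genes were taken from the more abundant ones. Each gene's spread was drawn independently of other genes and alike in every library, unlike the real excess in 1 library. With the spread of all 6 libraries, the quasi-likelihood test recovered 0% of the genes changed 2-fold and 63% of those changed 4-fold, with 1 false call among 64. With the spread of the 5 libraries without hormone-bound agarose replicate 3, it recovered 81% and 99%, with 14 false calls among 194.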

Results

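RNA sequencing was performed on CUTLL1, an established human T-cell lymphoblastic lymphoma line that carries an activated NOTCH1 gene. The cells had been exposed for 24 hours to agarose carrying the thyroid hormones T3 and T4, or to agarose alone. Hormone held on agarose is commonly used to keep it outside the cell, so the comparison addresses the response to thyroid hormone at the cell surface, where the study's title places integrin αvβ3 as a membrane receptor and angiogenesis as an outcome. Each group had 3 libraries. The libraries held 21390787, 23240286 and 24383589 counted reads for agarose replicates 1, 2 and 3, and 21908062, 22597107 and 7065362 for hormone-bound agarose replicates 1, 2 and 3. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values below are normalised CPM (read counts scaled to a common library size) as mean ± SD over 3 libraries, and log2 fold changes of hormone-bound agarose over agarose alone with their standard error (SE).

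CHRNA2, a subunit of neuronal nicotinic acetylcholine receptors, showed the clearest difference between hormone-bound agarose and agarose alone. Its mean was 8.54 ± 0.75 with the hormone and 1.71 ± 0.79 without it, a 5.03-fold difference. GPR97, an adhesion G protein-coupled receptor, stood at 6.19 ± 1.36 against 2.30 ± 0.39. CHI3L1, which encodes a secreted chitinase-like glycoprotein, was lower with the hormone, at 8.57 ± 0.82 against 16.0 ± 1.03. In each of these 3 genes every hormone library lay on the same side of every agarose library. None of the 13991 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so 0 genes were called higher and 0 lower. At an unadjusted p under 0.05 there were 66 genes, fewer than the share of 0.05 of the genes tested that chance alone would give. DESeq2 called 3 genes, namely CHRNA2 and GPR97 as higher and CHI3L1 as lower, edgeR's exact test called 1, CHRNA2, and limma-voom called 0.

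For CHRNA2 the log2 fold change was 2.33 ± 0.36, with an adjusted p of 0.911 in edgeR's quasi-likelihood test, 8.67e-06 in DESeq2 and 0.000153 in edgeR's exact test. It was 2.39 ± 0.32 without hormone-bound agarose replicate 3, and the gene had 31 to 59 reads per agarose library. The log2 fold change of GPR97 was 1.41 ± 0.28 and that of CHI3L1 -0.89 ± 0.20, and DESeq2 gave both an adjusted p of 0.0367. The other 7 of the 10 genes with the smallest p-values were higher in every hormone library than in every agarose library. ELOVL4, an elongase of very long chain fatty acids, was the most abundant of them, at 136 ± 29.8 against 75.4 ± 13.3. ADCY6, an adenylyl cyclase, reached 1.18 ± 0.24 against 0.51 ± 0.052, and GNG13, a G protein gamma subunit, 3.49 ± 1.20 against 1.49 ± 0.16. SHROOM4, an actin-associated protein, TMEM45B and TMC5, both membrane proteins, and TIRAP, an adaptor of Toll-like receptor signalling, had log2 fold changes of 1.20 ± 0.33, 1.07 ± 0.32, 0.90 ± 0.27 and 0.86 ± 0.26. Several of these genes rest on few reads. In hormone-bound agarose replicate 3 SHROOM4, ADCY6, TMEM45B, TIRAP and TMC5 had 5, 7, 8, 9 and 17 reads, and SHROOM4 had 6 to 8 per agarose library. None of these 7 was called by any of the tools named above. Across all genes tested, 295 were higher and 353 lower in every hormone library than in every agarose library, together 4.63% of the genes where chance gives 10%.

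**Figure D1:**
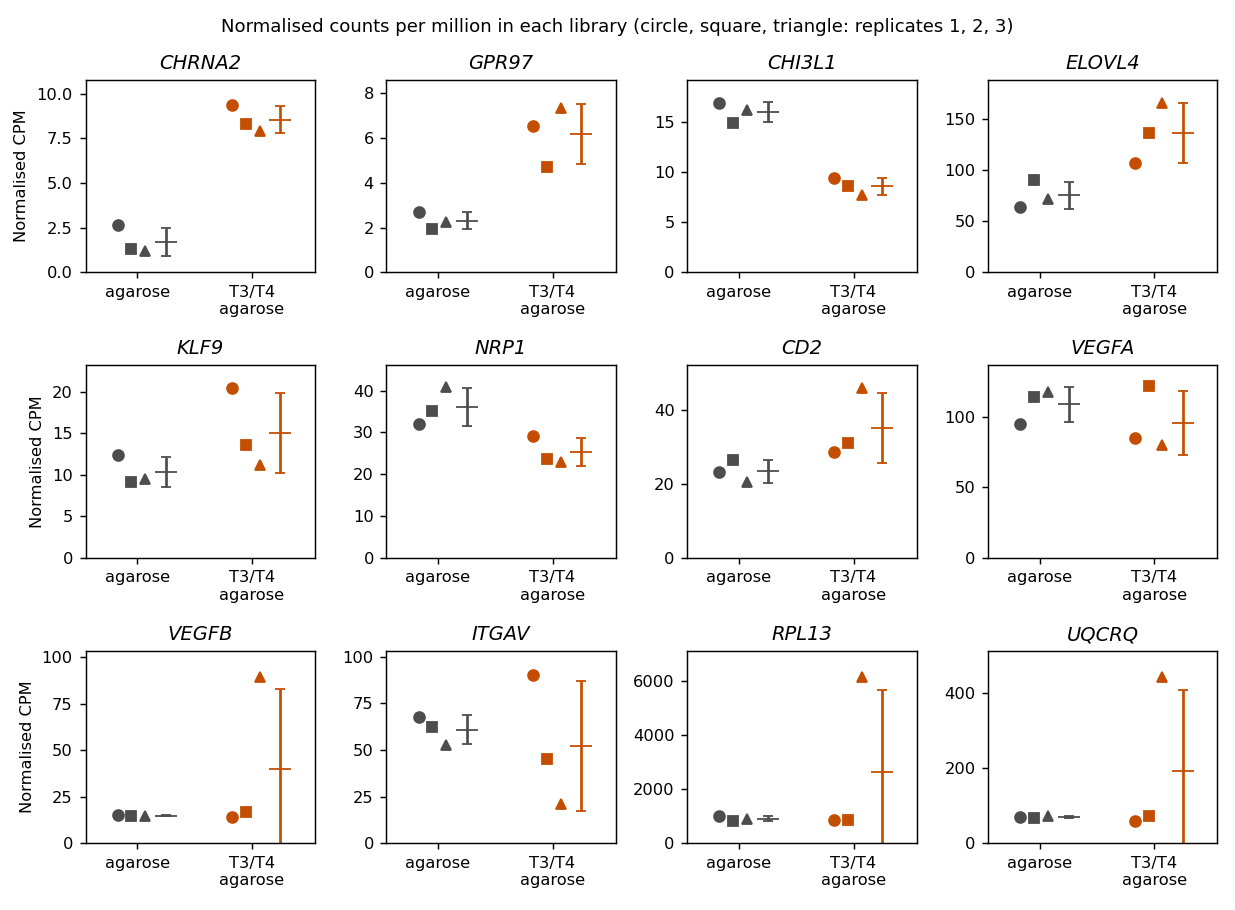
Normalised CPM (vertical axes, from 0) of 12 genes in the 3 agarose and 3 hormone-bound agarose libraries; circles, squares and triangles are replicates 1, 2 and 3, and the bar beside them is the mean ± SD. The groups do not overlap for CHRNA2, GPR97, CHI3L1, ELOVL4, NRP1 and CD2. For VEGFB, RPL13 and UQCRQ hormone-bound agarose replicate 3 alone lies far above the other 5 libraries.

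Hormone-bound agarose replicate 3 stood apart from the other 5 libraries. Its correlation with them across genes on the log2 CPM scale was between 0.890 and 0.907, while the other 5 correlated with each other at 0.987 to 0.994. Ribosomal protein genes took 22.3% of its reads and between 7.79% and 9.27% of the reads of the others. Relative to the mean of those 5 libraries, its genes with transcripts under 1 kb had a median deviation of 1.37 on the log2 scale and those over 4 kb one of -0.68. Without this library the biological coefficient of variation over all genes went from 31.9% to 13.9%, and 14178 genes could be tested. The quasi-likelihood test then also called 0 genes, with 214 at an unadjusted p under 0.05, again fewer than chance alone would give. DESeq2 called 3 (CHRNA2, EDEM3 and CHI3L1), edgeR's exact test 4 (CHRNA2, GPR97, EDEM3 and NEAT1) and limma-voom 0. EDEM3, which takes part in the disposal of misfolded glycoproteins, and the long non-coding RNA NEAT1 are named after their values were seen. Over these 5 libraries EDEM3 had a log2 fold change of 0.60 ± 0.10, with an adjusted p of 0.0171 in DESeq2, and NEAT1 one of 0.83 ± 0.17, with an adjusted p of 0.0200 in edgeR's exact test. In hormone-bound agarose replicate 3 itself EDEM3 stood at 47.9 CPM, below the 75.0 to 88.2 of the agarose libraries. In a principal component analysis of the other 5 libraries, replicate 1 of both groups lay together on component 2 (35.7% of variance). The values were -17.5 for agarose and -20.6 for hormone-bound agarose, against 11.5, 11.4 and 15.3 for the rest. On component 1 (37.3%) replicate 1 lay at -15.9 and 12.2, and replicate 2 at 23.1 and -18.6. A replicate block over these 5 libraries was not tested, so pairing stays open.

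**Figure D2:**
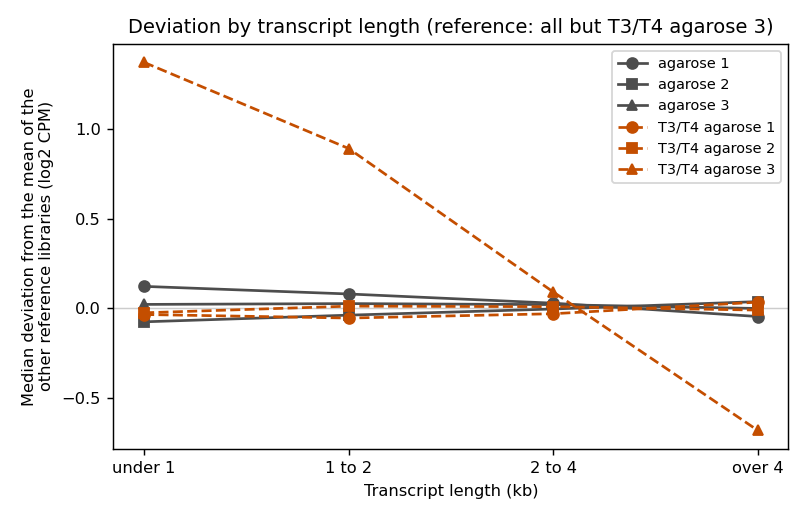
Median deviation of each library from the mean of the others, hormone-bound agarose replicate 3 never among them (vertical axis, log2 CPM), for genes in 4 bins of transcript length (horizontal axis, kb); solid lines are the agarose and dashed lines the hormone-bound agarose libraries. Hormone-bound agarose replicate 3 runs from 1.37 for transcripts under 1 kb to -0.68 for those over 4 kb, and the other 5 libraries stay between -0.074 and 0.12.

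Of the proposed receptor, the αv subunit was expressed and the β3 subunit was close to the limit of detection. ITGAV, which encodes αv, stood at 60.9 ± 7.76 in agarose alone and 52.2 ± 34.9 with the hormone, where its 3 libraries read 90.1, 45.4 and 21.3. ITGB3, which encodes β3, had 15, 5 and 8 reads in the agarose libraries and 12, 8 and 0 reads with the hormone, and the 0 allows up to 0.580 normalised CPM at the depth of that library. In agarose alone, some other integrin genes were far more abundant than ITGB3. ITGA4 stood at 350 ± 46.8, ITGB1 at 134 ± 6.73 and ITGB5, which encodes another partner of αv, at 18.7 ± 3.34. These 3 were named after their values were seen. ITGB8, a further partner of αv, stood at 0.61 ± 0.15. The log2 fold change of ITGAV was -0.21 ± 0.48, and 0.16 ± 0.26 without hormone-bound agarose replicate 3, with a 95% interval from -0.44 to 0.75. As a group, the 20 integrin genes tested had a median log2 fold change of 0.052 and a mean of 0.071, while camera placed them lower than other genes at an adjusted p of 0.883, so the signs differed. Their median deviation in hormone-bound agarose replicate 3 was -0.56, against 0.071 and 0.17 in replicates 1 and 2. Without replicate 3 the integrins were higher as a group, with a median of 0.17 over 21 genes of which 15 lay above 0 (camera adjusted p of 0.00928; adjusted p = 0.526 with an estimated correlation). With a correction for transcript length and GC content over the same 5 libraries, which overshoots the trend, the median was 0.13 and the call was lost (camera adjusted p of 0.141). With library quality weights over 6 libraries it was 0.16 (camera adjusted p of 0.00683; adjusted p = 0.908 with an estimated correlation). ITGAE, the αE subunit, read 28.9 and 31.9 in hormone replicates 1 and 2 and 131 in replicate 3. ITGB2, the β subunit of leukocyte integrins, had a log2 fold change of 0.33 ± 0.26, and ITGA6, the α6 subunit, one of -0.27 ± 0.23.

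No gene of thyroid hormone reception and transport passed the test, and over 6 libraries their lists did not pass either. THRA, a nuclear thyroid hormone receptor, was at 29.7 ± 1.84 in agarose alone and 23.4 ± 9.73 with the hormone, where replicate 3 read 12.4. THRB, the other nuclear receptor gene, had 1 read in all 6 libraries together. The list of receptors, transporters and deiodinases had a median of -0.27 over 15 genes (camera adjusted p of 0.155). Its median deviation was -0.78 in hormone-bound agarose replicate 3, and its median was 0.025 over the other 5 libraries, with the camera test still on the lower side at an adjusted p of 0.917. Without hormone-bound agarose replicate 2 the list fell, with a median of -0.36 (camera adjusted p of 0.0347; adjusted p = 0.870 with an estimated correlation). KLF9, a transcription factor gene induced by thyroid hormone in many cell types, stood at 15.1 ± 4.83 with the hormone and 10.3 ± 1.78 without it. Its log2 fold change was 0.56 ± 0.29, and without hormone-bound agarose replicate 3 it was 0.73 ± 0.22, with an unadjusted p of 0.0118. The 8 nuclear receptor targets tested had a median of -0.063 and a mean of 0.052 with camera on the higher side (adjusted p of 0.883), a median deviation of -0.31 in replicate 3, and a median of 0.12 without it (camera adjusted p of 0.0665). Other members were UCP3, a mitochondrial carrier, at 3.37 ± 0.47 against 2.39 ± 0.40, and BCL3, an NF-kB cofactor, with a log2 fold change of 0.77 ± 0.42 that was 0.15 ± 0.14 without replicate 3. ME1, a malic enzyme, read lower, at 0.51 ± 0.15 against 0.85 ± 0.36, with log2 fold changes of -0.66 ± 0.43 over 6 libraries and -0.59 ± 0.45 without replicate 3.

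No angiogenic factor or receptor passed the test. VEGFA, the main vascular endothelial growth factor, was at 95.7 ± 22.9 with the hormone and 109 ± 12.2 without it. Its log2 fold change was -0.19 ± 0.22, and -0.066 ± 0.17 without hormone-bound agarose replicate 3, with a 95% interval from -0.46 to 0.33. VEGFB showed a log2 fold change of 1.41 ± 0.70 that came from 1 library. Hormone-bound agarose replicates 1, 2 and 3 read 14.3, 16.8 and 89.3 against 14.9 ± 0.33 in agarose alone, and the log2 fold change was 0.068 ± 0.14 without replicate 3. VEGFC, a lymphangiogenic factor, was at 5.64 ± 1.42 against 6.28 ± 0.26. NRP1, a co-receptor for VEGF, was lower in every hormone library, at 25.2 ± 3.31 against 36.0 ± 4.55, with a log2 fold change of -0.51 ± 0.20, an unadjusted p of 0.0361 and an adjusted p of 0.911 in edgeR's quasi-likelihood test. SPHK1, a sphingosine kinase, read 12.7 and 16.3 in hormone replicates 1 and 2 and 51.2 in replicate 3. The 25 angiogenic genes tested had a median of 0.019, with 13 above 0 (camera adjusted p of 0.961), and a median of 0.013 without replicate 3, where the mean of -0.014 and camera pointed lower (adjusted p of 0.506). Hypoxia response genes had a median of -0.027 and a mean of 0.0059 over 22 genes with camera on the lower side (adjusted p of 0.846), and a median of 0.087 without replicate 3 (adjusted p of 0.592). Among them EPAS1, a hypoxia-inducible factor, was at 187 ± 64.1 against 243 ± 40.4. Adhesion and actin cytoskeleton genes had a median of 0.0037 over 26 genes with camera on the lower side (adjusted p of 0.883). Within this list PARVG, a parvin of the integrin-linked kinase complex, was higher in every hormone library, at 5.81 ± 0.32 against 4.04 ± 0.73, and SPP1, the integrin ligand osteopontin, lower in every one, at 53.8 ± 6.54 against 63.8 ± 2.77. Their log2 fold changes were 0.52 ± 0.23 and -0.25 ± 0.17, and neither passed the test.

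Cytosolic ribosomal protein genes and nuclear-encoded oxidative phosphorylation genes rose as groups over the 6 libraries, and this rise came from hormone-bound agarose replicate 3. The median log2 fold change was 0.94 over 77 ribosomal protein genes, of which 75 lay above 0 (camera adjusted p of 2.81e-14; adjusted p = 0.928 with an estimated correlation). It was 0.89 over 53 oxidative phosphorylation genes, of which 50 lay above 0 (camera adjusted p of 2.02e-08; adjusted p = 0.928 with an estimated correlation). The median deviation of the ribosomal list from the agarose libraries was 1.96 in replicate 3 and -0.011 and -0.19 in replicates 1 and 2, and that of the oxidative phosphorylation list was 1.89 against -0.11 and -0.087. RPL13, a protein of the large ribosomal subunit, read 873, 882 and 6156 in the 3 hormone libraries and 920 ± 106 in agarose alone, and UQCRQ, a subunit of respiratory complex III, read 59.6, 72.8 and 443 against 69.9 ± 3.33. Without replicate 3 both lists fell, each with a median of -0.081, and 7 of the 77 and 5 of the 53 genes lay above 0 (camera adjusted p of 3.64e-07 and 3.50e-07; adjusted p = 0.869 and adjusted p = 0.438 with an estimated correlation). Corrected for transcript length and GC content, these medians were -0.024 and, over 48 genes with a length, -0.030 (camera adjusted p of 0.214 and 0.0243; adjusted p = 0.885 for both with an estimated correlation). No single gene of either list passed the test or had an unadjusted p under 0.05 with or without that library. The summed level of the ribosomal list ran from 77855 to 92681 CPM in the other 5 libraries.

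**Figure D3:**
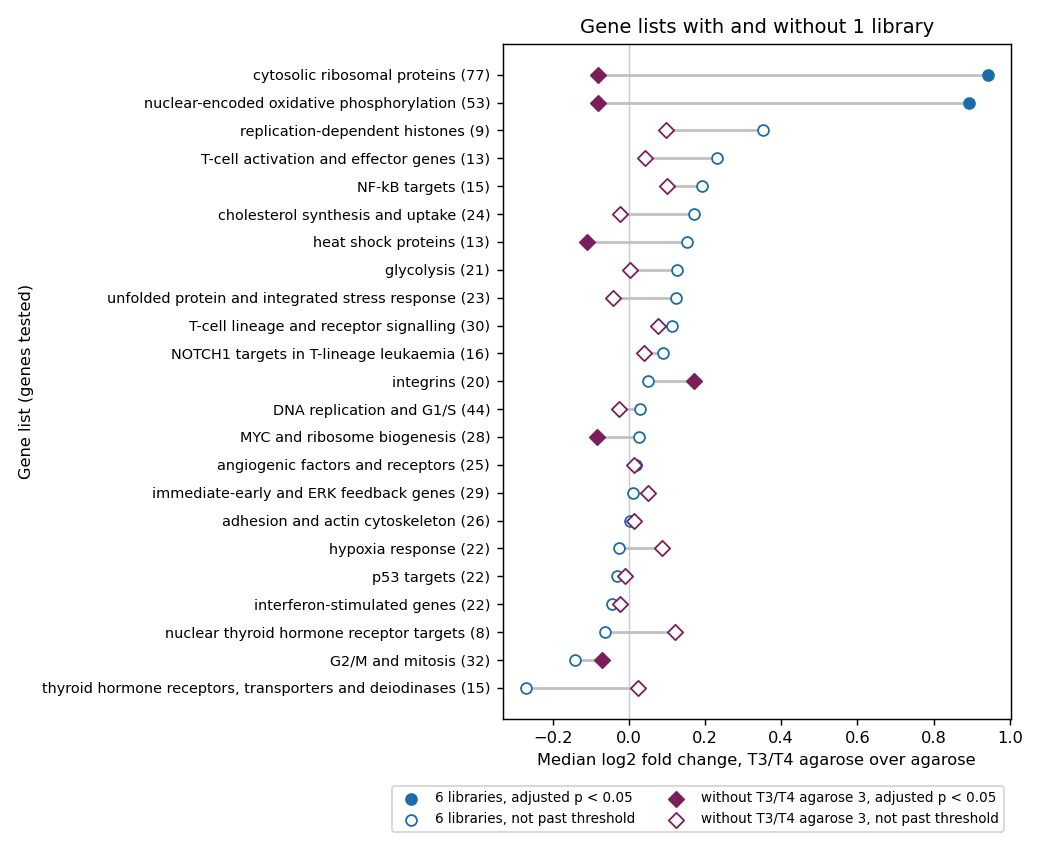
Median log2 fold change of hormone-bound agarose over agarose alone (horizontal axis) for 23 gene lists (vertical axis, genes tested in brackets), over 6 libraries (circles) and without hormone-bound agarose replicate 3 (diamonds); filled symbols passed a camera adjusted p of 0.05 with the preset correlation. The ribosomal and oxidative phosphorylation lists move from 0.94 and 0.89 to -0.081 when that library is left out, and with an estimated correlation 0 lists passed in either case.

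Growth and cell cycle lists did not pass over 6 libraries in the quasi-likelihood fit. PCNA, the replication clamp, was at 786 ± 340 against 568 ± 18.8, with 1170 in hormone-bound agarose replicate 3, MKI67, a proliferation marker, at 1131 ± 488 against 1362 ± 187, with 582 in that library, and MYC at 232 ± 29.2 against 227 ± 8.12. CCND1, a cyclin, had between 1 and 6 reads in 5 libraries and 0 in hormone-bound agarose replicate 3. DNA replication and G1/S genes had a median of 0.029 over 44 genes (camera adjusted p of 0.846) and of -0.026 without hormone-bound agarose replicate 3 (adjusted p of 0.146), with CCND3, another cyclin, at 633, 821 and 1824 in the hormone libraries against 600 ± 43.4. The G2/M and mitosis list had a median of -0.14 over 32 genes (camera adjusted p of 0.155) and the MYC and ribosome biogenesis list a median of 0.026 over 28 genes with camera on the lower side (adjusted p of 0.883). Without hormone-bound agarose replicate 3 both lists fell by small amounts. The G2/M median was -0.070, with 8 of 32 genes above 0 (camera adjusted p of 0.00199; adjusted p = 0.869 with an estimated correlation), and the MYC list median was -0.084, with 3 of 28 above 0 (camera adjusted p of 3.52e-05; adjusted p = 0.795 with an estimated correlation). With the length and GC correction over those 5 libraries the medians were -0.044 and -0.081 (camera adjusted p of 0.0498 and 0.000291; adjusted p = 0.885 for both with an estimated correlation). The G2/M list also fell without agarose replicate 1, with a median of -0.24 (camera adjusted p of 0.00224; adjusted p = 0.934 with an estimated correlation), and without hormone-bound agarose replicate 2, with one of -0.25 (camera adjusted p of 0.0383; adjusted p = 0.870 with an estimated correlation). The G2/M median deviation was -0.19, 0.14 and 0.063 in agarose replicates 1, 2 and 3. In hormone-bound agarose replicates 1, 2 and 3 it was -0.23, 0.039 and -0.28. The 2 groups thus overlapped, and the fall was larger when the lowest agarose library was left out. Both lists also fell over 6 libraries with library quality weights in limma-voom. The medians were then -0.064 and -0.13 (camera adjusted p of 0.0405 and 0.000130; adjusted p = 0.938 and adjusted p = 0.908 with an estimated correlation). FBL, the methyltransferase fibrillarin, read 500 and 432 in hormone replicates 1 and 2 and 2090 in replicate 3, against 512 ± 19.6 in agarose alone. Glycolysis genes had a median of 0.13 over 21 genes (camera adjusted p of 0.883) and of 0.0024 without replicate 3 (adjusted p of 0.506), with GAPDH at 5010, 5324 and 13270 in the hormone libraries.

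T-cell and NOTCH1 genes did not pass as groups over 6 libraries in the quasi-likelihood fit. NOTCH1 itself was at 384 ± 174 with the hormone, where replicates 1, 2 and 3 read 271, 584 and 298, and at 339 ± 88.0 without it. Its 16 listed targets had a median of 0.090 (camera adjusted p of 0.883), and of 0.041 without replicate 3 (adjusted p of 0.695). Among them HES4, a transcriptional repressor, read 12.8, 35.6 and 54.3 in the hormone libraries against 18.4 ± 3.52, and DTX1, a regulator of NOTCH signalling, read 131, 232 and 314 against 150 ± 4.28. The T-cell lineage and receptor signalling list had a median of 0.11 over 30 genes, of which 19 lay above 0 (camera adjusted p of 0.537), and a median of 0.076 with 25 above 0 without hormone-bound agarose replicate 3 (camera adjusted p of 0.0928). It passed as higher over those 5 libraries with the length and GC correction, which overshoots the trend, with a median of 0.10 (camera adjusted p of 0.00686; adjusted p = 0.885 with an estimated correlation). It also passed with library quality weights in limma-voom over 6 libraries, with one of 0.20 (camera adjusted p of 2.41e-06; adjusted p = 0.938 with an estimated correlation). The list's median deviation was -0.14, 0.26 and 0.22 in hormone-bound agarose replicates 1, 2 and 3. In agarose replicates 1, 2 and 3 it was -0.040, 0.11 and -0.036. The hormone libraries thus did not all rise, and among them the weights favoured replicate 2. CD2, an adhesion receptor of T cells, was higher in every hormone library, at 35.3 ± 9.52 against 23.5 ± 3.03, with a log2 fold change of 0.58 ± 0.24, an unadjusted p of 0.0497 and an adjusted p of 0.911 in edgeR's quasi-likelihood test. CD3D, a chain of the T-cell receptor complex, stood at 1937 in hormone-bound agarose replicate 3 and between 317 and 456 in the other 5 libraries. T-cell activation and effector genes had a median of 0.23 over 13 genes (camera adjusted p of 0.537) and of 0.043 without replicate 3 (adjusted p of 0.592), among them IL2RA, the interleukin-2 receptor alpha chain, at 1422 ± 371 against 973 ± 130. GZMB, the protease granzyme B, read 809, 752 and 2634 in the hormone libraries against 703 ± 51.3.

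Stress and signalling lists did not pass over 6 libraries in the quasi-likelihood fit with its low-count filter. Heat shock genes had a median of 0.15 over 13 genes (camera adjusted p of 0.846), with a median deviation of 0.47 in hormone-bound agarose replicate 3. Without that library their median was -0.11 and 0 of 13 genes lay above 0 (camera adjusted p of 0.00154; adjusted p = 0.804 with an estimated correlation). With library quality weights over 6 libraries the median was -0.14 (camera adjusted p of 0.00683; adjusted p = 0.938 with an estimated correlation). The chaperone gene HSPE1 read 41.9, 39.3 and 212 in the hormone libraries. The median was 0.13 for unfolded protein and integrated stress response genes (23 genes, camera adjusted p of 0.537), 0.17 for cholesterol synthesis and uptake (24 genes, adjusted p of 0.846) and 0.19 for NF-kB targets (15 genes, adjusted p of 0.595). In hormone-bound agarose replicate 3 their deviations were 0.34, 0.46 and 0.47, and without it the medians were -0.041, -0.022 and 0.10 (camera adjusted p of 0.506 for each). Over 6 libraries it was 0.011 for immediate-early and ERK feedback genes (29 genes, adjusted p of 0.883), the class induced by growth factor signalling, and 0.049 without replicate 3 (adjusted p of 0.695). For p53 targets the median was -0.030 and the mean 0.085 with camera on the lower side (22 genes, adjusted p of 0.883), and for interferon-stimulated genes the median was -0.044 and the mean 0.093 with camera on the lower side (22 genes, adjusted p of 0.860). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had a median of 0.35 over 9 genes, all above 0 (camera adjusted p of 0.155), and a deviation of 0.44 in replicate 3, without which the median was 0.098 (adjusted p of 0.628). With no low-count filter they passed as higher, with a median of 0.34 over 26 genes (camera adjusted p of 0.00579; adjusted p = 0.919 with an estimated correlation). DDIT3, a stress-induced transcription factor, read 25.0, 25.0 and 121 in the hormone libraries, and JUND, an AP-1 transcription factor, 20.7, 23.3 and 101. Adjusted over the list alone, 0 genes of the 23 lists passed in the quasi-likelihood test, as over all genes tested, and fry, which asks whether a list's genes move on balance in 1 direction, called 0 lists with or without hormone-bound agarose replicate 3.

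Markers of other cell types stayed low in every library. The summed level of B-cell markers was between 0.283 and 0.935 CPM, that of erythroid markers between 1.64 and 2.57, that of stromal and endothelial markers between 5.68 and 7.26 and that of myeloid markers between 34.8 and 55.5, all per library total without TMM scaling. Among myeloid markers CD68 stood at 20.9 ± 3.46 and CSF1R at 13.3 ± 4.13 normalised CPM in agarose alone. With no low-count filter the myeloid list could be tested with 10 genes and passed as higher, with a median of 0.57 (camera adjusted p of 0.0183; adjusted p = 0.919 with an estimated correlation). Of these, 6 lay below the filter used elsewhere, where fitted fold changes rest on few reads. Per library total, hormone-bound agarose replicate 3 was the lowest library for B-cell and myeloid markers. With TMM scaling it was the highest for CD68, at 27.6 normalised CPM, so this ranking depends on the scaling. The T-cell lineage list summed to between 4871 and 6182 CPM.

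The authors' deposited table of the same comparison listed 1 gene past an adjusted p of 0.05, CHRNA2, with the authors' log2 fold change of 2.38 and adjusted p of 0.00282. An unadjusted p under 0.05 was given to 658 genes in the authors' deposited table. The sign for CHRNA2 was the same in the quasi-likelihood test, where the gene did not pass. Across 13982 genes present in both, the log2 fold changes of the authors' deposited table and those computed here had a Pearson correlation of 0.841 and a Spearman correlation of 0.851, which describes genes and not independent replicates. For VEGFB the authors' deposited table gave a log2 fold change of 0.61, against 1.41 here over 6 libraries and 0.068 without hormone-bound agarose replicate 3, and for RPL13 it gave 0.60, against 1.52 and -0.062.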

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

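Library quality weights, the length and GC corrections, the quasi-likelihood test without its legacy option, and DESeq2, the exact test, limma-voom and fry over the 5 libraries without hormone-bound agarose replicate 3, and the estimated correlation in any setting but the quasi-likelihood fit over 6 libraries, were chosen after the result was seen. The count of 0 genes past the threshold held in the quasi-likelihood test with other scalings, other filters, each library left out (range 0 to 0), a 1.5-fold minimum, an adjusted p under 0.01 and both length corrections, and in limma-voom. At an unadjusted p under 0.05 the count ran from 29 to 820 with 1 library left out, the highest without hormone-bound agarose replicate 1. DESeq2 called 3 genes (2 higher, 1 lower), the exact test 1 (1 higher) and library quality weights 1 (1 higher). Over 5 libraries DESeq2 called 3 (2 higher, 1 lower) and the exact test 4 (4 higher). Adjusted over the list alone, 0 genes became 2 with quality weights (NRP1 lower, KLF9 higher), 2 with DESeq2 over 5 libraries (KLF9 higher, GZMA lower) and 1 with the exact test over 5 libraries (KLF9). CHRNA2 had log2 fold changes from 2.13 to 2.77 throughout, and adjusted p-values from 9.90e-08 in the exact test over 5 libraries to 0.9996 in the quasi-likelihood test over those libraries. With the replicate block 0 genes passed, 31 at an unadjusted p under 0.05, and 2 lists. Deviations of same-numbered libraries correlated at -0.051, 0.066 and 0.074, never the best match, but the outlying library leaves pairing undecided.

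The 2 lists past the camera threshold became 4 with no low-count filter (adding histones and myeloid markers), 5 with quality weights, 5 over 5 libraries with the length and GC correction, 6 over 5 libraries with limma-voom, and from 2 to 6 with 1 library left out (4 without hormone-bound agarose replicate 2, 6 without replicate 3). They became 0 with fry over 6 or 5 libraries, and 0 with an estimated correlation there and in each of 7 further settings in which lists had passed (no low-count filter, agarose replicate 1 or hormone-bound agarose replicate 2 left out, quality weights, the length and GC correction over 6 and 5 libraries, limma-voom over 5). List tests were not run with DESeq2 or the exact test. The camera direction turned against a call, in 6 libraries or in the alternative, in 4 lists with these medians. Without hormone-bound agarose replicate 3 they were -0.081 for ribosomal proteins (the same in the estimated correlation and fry fits), -0.081 for oxidative phosphorylation (likewise) and -0.11 for heat shock proteins, and for integrins 0.17 with the opposite camera direction. With quality weights they were -0.054, -0.065, -0.14 and 0.16, with limma-voom over 5 libraries -0.079, -0.083, -0.11 and 0.19, and with the length and GC correction over 5 libraries -0.024, -0.030 and -0.080 for the first 3. Each of these settings leaves out or weights down hormone-bound agarose replicate 3. With no call on either side it also turned in settings that keep that library, given here for lists called in some setting and, under the length and GC correction, for all. With that correction over 6 libraries the medians were 0.072 for integrins, now higher, and for lists now lower -0.023 (T-cell lineage), -0.041 (histones), 0.0030 (angiogenic), -0.011 (glycolysis), -0.041 (NOTCH1 targets), -0.039 (immediate-early) and 0.067 (NF-kB). Integrins turned without agarose replicate 1 (0.089), the T-cell lineage without hormone-bound agarose replicate 2 (-0.020), and the MYC list without agarose replicate 3 (0.034), hormone-bound agarose replicate 1 (0.081) or replicate 2 (0.058). Without hormone-bound agarose replicate 3 further medians changed sign. That of MYC and ribosome biogenesis went from 0.026 to -0.084, with camera lower in both. Lists called in neither case went from 0.13 to -0.041 (unfolded protein), 0.17 to -0.022 (cholesterol), 0.029 to -0.026 (DNA replication), -0.027 to 0.087 (hypoxia), -0.27 to 0.025 (thyroid hormone receptors and transporters) and -0.063 to 0.12 (nuclear receptor targets). With 1 library left out in turn the medians of the 4 lists named first ranged over -0.081 to 1.28, -0.081 to 1.21, -0.11 to 0.24 and -0.10 to 0.17. Among 93 named genes, 42 changed sign under some alternative, in 186 of 1946 values, and none of those was called in either direction. In simulation a 2-fold change was recovered for 0% of changed genes at the depth and spread of the 6 libraries and for 81% at those of the 5, and 0 genes passed in both real fits. The simulation changed 200 abundant genes at once with independent spread, so these shares are not the power of the real fits. In the real fit over 5 libraries CHRNA2, with a log2 fold change of 2.39, had an adjusted p of 0.9996 in the quasi-likelihood test.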

Other observations

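The tests on transcript length alone, a rise in every hormone-treated culture, CHRNA2, KLF9 and other splits were chosen after the result was seen. So were the second length definition and the length and GC correction of the gene lists. The tests on depth, length with GC content, other cell types and matched lists were set before their own results were seen. The patterns they address were found in these data.

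The genes of this paragraph were chosen singly after their values were seen. NEAT1, the scaffold RNA of paraspeckles, read 546 and 363 in hormone-bound agarose replicates 1 and 2 against 256 ± 28.4 in agarose alone, and MIAT, another long non-coding RNA that was called by no tool, read 381 and 389 against 303 ± 15.8. In replicate 3 they read 276 and 138. The log2 fold changes over 5 libraries were 0.83 ± 0.17 and 0.35 ± 0.085, and over 6 libraries 0.63 ± 0.28 and -0.0021 ± 0.39. GZMA, which encodes the protease granzyme A, read 78.2, 80.9 and 216 in the hormone libraries against 101 ± 4.42. Its log2 fold change was -0.33 ± 0.089 over 5 libraries and 0.31 ± 0.41 over 6, so its direction turned with replicate 3.

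Hormone-bound agarose replicate 3 stood apart from the other 5 libraries. Lower depth is argued against, because other libraries thinned to its total still correlated with the rest at 0.983 or more, above its 0.890 to 0.907. RNA from B, myeloid, erythroid, stromal or endothelial cells is argued against too, since 0 of 4 marker lists exceeded 2 times the highest other library. Its deviation fell by 0.428 per doubling of transcript length, where no other library exceeded 0.051 in size, so loss of long transcripts may account for part of the difference. Length and GC content are argued against as the whole, because after correction for them the library's highest correlation with another was 0.934, below the 0.989 or more among the others. That correction overshoots the trend, which may lower the 0.934. The hormone on its own is argued against too, since hormone-bound agarose replicates 1 and 2 had the same exposure. They correlated with the agarose libraries at 0.989 to 0.994 and with replicate 3 at 0.890 and 0.907. What else set this library apart stays open.

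The ribosomal protein and oxidative phosphorylation lists rose over 6 libraries in camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.928 for both). A rise in every hormone-treated culture is argued against, since the highest median deviation of both lists in replicates 1 and 2 was -0.011. Transcript length and GC content together may explain part of it. Their joint correction brought the ribosomal median from 0.94 to 0.20, and the other from 0.89 over 53 genes to 0.17 over the 48 with a length (camera adjusted p of 0.000334 and 0.0260; adjusted p = 0.968 for both with an estimated correlation). That correction overshoots the trend, so these medians do not measure the share explained. Transcript length as the whole cause is argued against, as far as the matching reached. In replicate 3 the medians exceeded the upper end of the central 95% of 1000 lists matched on length and expression by at least 0.42 on the log2 scale. Matching was by bins of length, so differences in length within a bin were not tested. With the shortest principal transcript as the length, the medians of the matched lists fell from 1.33 and 1.31 to 0.39 and 0.33. That length tracked the deviation less closely, so the larger excess it gave adds no support. Other properties of short, abundant transcripts stay open.

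CHRNA2 was higher with the hormone in 3 of 3 libraries. The outlying library is argued against as its source, since the log2 fold change was 2.39 ± 0.32 without it. A constant share of reads from a neighbouring gene is argued against, since PTK2B and EPHX2, on either side of CHRNA2, had log2 fold changes of 0.25 ± 0.12 and 0.13 ± 0.11 over 5 libraries. A share that changed between the groups was not tested. It cannot be excluded by fold changes, as both neighbours were far more abundant, at 30.3 and 46.1 CPM in agarose alone. A response of CHRNA2 to the hormone may be considered as a hypothesis only, found and tested on the same libraries. The gene's level in agarose alone was low, at about 1.71 CPM from 31 to 59 reads per library.

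As a further hypothesis, the higher KLF9 in hormone-bound agarose replicates 1 and 2 may reflect hormone that reached nuclear receptors. The list of nuclear receptor targets, which holds KLF9, was higher over 5 libraries with a camera adjusted p of 0.0665, so the hypothesis is neither supported nor excluded, and KLF9 also responds to other signals. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest of the other splits 0, and since no split can give fewer this says nothing about chance. At an unadjusted p under 0.05 the real split gave 66 genes and the other splits 28 to 693. The smallest unadjusted p in the quasi-likelihood test was 0.000369 for the real split, against 8.43e-05 in the split with the lowest. For lists the real split gave 2 and the other splits 2 to 9, so all 10 splits gave as many or more. Camera with the preset correlation thus called lists in every split, including those that mix the groups.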
